A study of Mus musculus with 4 samples.

How the data were processed

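The data were gene counts of 4 bulk RNA-seq libraries of sorted mouse periosteal cells, 2 of wild-type and 2 of Sfrp4-/- mice, each made from cells pooled from 3 mice. Per the labels' protocols, periosteum of long bones was digested with collagenase, cells were sorted by surface markers and the GFP lineage label, and ultra-low-input mRNA libraries were made with a SMARTer kit. This chemistry amplifies whole cDNA from small amounts of RNA and, per the labels, the libraries are not directional, so reads of overlapping genes on opposite strands cannot be told apart. The authors deposited raw counts per gene, whole numbers that had not been normalized, together with gene coordinates, gene length in bases and biotype. Per the submitters' processing notes, CASAVA, HISAT2 2.0.5, featureCounts 1.00-p3 and DESeq2 1.20.0 were used with the mm10 build. The role of each tool, the counting options and the annotation release are not given in the sources used here. Of 54532 gene identifiers, 54495 (99.9%) were found in GENCODE M21 (GRCm38, the assembly that mm10 denotes), and 53585 of those (98.3%) had the same coordinates.

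Groups and replicate numbers were taken from the sample titles. The libraries held 17119332 to 18750003 counts. Counts of each pair of libraries differed by more than sampling noise (chi-square per degree of freedom 56.3 to 254.9), so each library was used as a replicate. The sequences carry no molecular identifiers in the sources used here, and intervals and floors cover counting error only. The main test was edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr (13737 genes, 12394 of them protein coding), TMM factors (0.877 and 0.972 in wild-type, 0.989 and 1.19 in Sfrp4-/- libraries), glmQLFit and glmQLFTest with genotype as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. The common dispersion was 0.173, a biological coefficient of variation of 41.5%. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values use totals multiplied by the TMM factors. Where a genotype had 0 counts, a bound was computed against a floor of 3 counts over the group, and where it had 10 or fewer, a 95% exact binomial interval was given for the ratio.

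A total of 34 gene lists with at least 3 measured members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 34 lists. Of the 733 entries in the lists, 3 symbols (Ccn4, Rigi and Ahsp) had no match in the table. Of the 8 lists that passed, 0 held with an estimated correlation (lowest adjusted p = 0.356) and 0 passed with fry, which tests whether the genes of a list move on balance in a single direction. For each list, calls were counted over all genes and adjusted over the list alone. The groups, the tests, the lists, the rule for naming genes and the alternatives were fixed before the data were examined. Additions made later are named as such. The text names Sfrp4 and the genes of the sort; in each direction the 5 protein-coding genes with the lowest unadjusted p, a mean of at least 5 CPM and both libraries of a genotype above both of the other, since none passed the test; 2 members of each list with the lowest unadjusted p; and 4 more from each of the 4 Wnt lists. This gave 92 genes. Of these, 12 share over 5% of their exon bases with another annotated gene on either strand. Counts of globin, osteocalcin (Bglap), histone and Gpr137b genes are uncertain because of near-identical copies.

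Alternatives were median-of-ratios (RLE) factors, library totals alone, no filter on low counts, at least 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, robust edgeR, the replicate number as a block, protein-coding genes only, no mitochondrially encoded genes, leaving out each library, an adjusted p under 0.10, a test against 1.5-fold, and the set tests above. Gene calls of DESeq2 were made without the filter on low counts, while its list tests used the filtered genes. With a library left out, the lone library of that genotype is assumed to vary like the other genotype's. Trends with GC content of the longest transcript, gene length and abundance were fitted over all genes with mgcv 1.9.3. Reference tables were made with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

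The gene test was tested on simulated data, drawn for the 13737 genes from the means, depths and gene-wise dispersions of these libraries. It recovered 6 of 67 genes changed 2-fold (8.96%), 40 of 67 changed 4-fold (59.7%) and 61 of 66 changed 8-fold (92.4%), with 16 false calls. The simulated libraries had no structure by replicate number, unlike the real ones, so these shares may not hold for the real comparison. In the real test Sfrp4 did not pass (edgeR adjusted p = 0.377) at a log2 fold change of -3.08. A simulated list of 20 genes raised 2-fold had an adjusted p of 4.53e-19 in camera with the preset correlation and 0.498 with an estimated correlation, and 0 of 20 unchanged lists were called. The estimated-correlation test therefore missed a list that had been raised in this design. Genes were drawn independently of each other, so false calls at the preset correlation in lists of correlated genes were not tested. In the real data the estimated correlation was 0.655 in the extracellular matrix list and 0.584 in the chondrocyte list.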

Results

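Bulk RNA sequencing was used to compare sorted periosteal cells of wild-type mice with those of mice lacking Sfrp4, a gene for a secreted protein that binds Wnt ligands. The periosteum is the fibrous and cellular sheet on the outer surface of bone. Long bones came from mice aged 4 weeks that carried a Cre recombinase under the control of Ctsk and the mTmG reporter, so that cells of the Ctsk lineage expressed GFP. The sorted population was GFP-positive and CD200-positive, and it was negative for CD45, CD31, Ter119, Thy1.2, 6C3 and CD105. The study calls these cells periosteal stem cells. There were 2 libraries per genotype, each made from the pooled cells of 3 mice. Because the mice were pooled, the p-values measure the spread between the 2 pools of each genotype, not the spread between single animals. The 4 libraries held 17119332 and 17669306 counts in wild-type replicates 1 and 2, and 18750003 and 17341775 counts in Sfrp4-/- replicates 1 and 2. A single count was worth 0.0486 to 0.0667 CPM (counts scaled to a common library size). Genes with at least 1 count numbered 16333 and 15400 in the wild-type libraries and 17359 and 20080 in the Sfrp4-/- libraries. Sparc, Col1a1 and Col1a2, which encode abundant proteins of bone matrix, took 31.5% and 20.1% of the wild-type counts and 25.4% and 15.3% of the Sfrp4-/- counts.

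The deleted gene was examined first, as a check of the labels. Sfrp4 (ENSMUSG00000021319, plus strand of chromosome 13, 19623104 to 19632994, mm10) was measured at 90.8 and 108 CPM in the wild-type libraries and at 11.4 and 12.1 CPM in the Sfrp4-/- libraries. The group means were 99.2 ± 11.8 and 11.8 ± 0.509 CPM (SD, n = 2 each). The log2 fold change, taken throughout as Sfrp4-/- minus wild-type, was -3.08 ± 0.31 (SE). Its 6 annotated exons overlap no exon of another gene, and 211 and 249 counts remained in the Sfrp4-/- libraries. The labels do not say which part of the gene is deleted. Although both Sfrp4-/- libraries lay far outside the wild-type range, Sfrp4 did not pass the edgeR quasi-likelihood test over all genes (Benjamini-Hochberg adjusted p = 0.377). It passed with DESeq2 (adjusted p = 2.58e-12) and with edgeR (adjusted p = 2.24e-10), both without a filter on low counts. On the filtered genes it passed with the replicate number as a block (edgeR adjusted p = 0.0218). Its adjusted p ranged from 2.58e-12 to 0.997 over the alternatives.

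Of the genes of the sort, Ctsk and Cd200 were abundant in all 4 libraries and none passed the test. Ctsk, which encodes cathepsin K and drives the lineage label, was at 1552 ± 704 CPM in wild-type and 1573 ± 158 CPM in Sfrp4-/- libraries (SD, n = 2 each), a log2 fold change of 0.019 ± 0.42 (SE). Cd200 was at 577 ± 129 and 453 ± 16.1 CPM (log2 fold change -0.35 ± 0.33). Genes of surface proteins used for exclusion were far below Ctsk and Cd200. Ptprc, encoding CD45, lay between 5.87 and 9.45 CPM, Pecam1, encoding CD31, between 0.535 and 1.93 CPM, and Eng, encoding CD105, between 0.291 and 2.80 CPM. Their log2 fold changes were 0.18 ± 0.42, -0.62 ± 0.99 and -0.19 ± 1.16. Thy1 had 0 counts in every library, and Enpep, encoding 6C3, had 17, 0, 6 and 0 counts, so neither entered the test. The 5 tested genes of the sort did not shift as a list (median -0.19, camera adjusted p = 0.622).

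Apart from Sfrp4, the protein-coding genes that separated the genotypes most clearly included 5 with higher and 4 with lower values in both Sfrp4-/- libraries. Qprt, an enzyme of NAD synthesis, was at 1.42 ± 0.354 CPM in wild-type and 9.53 ± 2.55 CPM in Sfrp4-/- libraries (SD, n = 2 each; log2 fold change 2.75 ± 0.51, SE). C1qc, a complement subunit made by macrophages, was at 1.17 ± 0.989 and 11.0 ± 0.412 CPM (3.21 ± 0.67). The mitotic genes Birc5 and Nusap1 were at 20.9 ± 2.11 against 53.4 ± 11.8 CPM (1.35 ± 0.31) and at 4.26 ± 2.65 against 19.9 ± 5.55 CPM (2.22 ± 0.53). Tmcc2 was at 11.5 ± 1.27 against 31.6 ± 2.07 CPM (1.46 ± 0.30). In the other direction, Col10a1, the collagen of hypertrophic cartilage (ENSMUSG00000039462, chromosome 10, 34389981 to 34397085), had 1064 and 67 counts in the wild-type libraries and 2 and 3 counts in the Sfrp4-/- libraries. The ratio of its pooled levels was 275, with a 95% interval of 117 to 848 from counting error alone, and the wild-type libraries themselves differed widely, at 71.0 and 3.91 CPM. Alcam, an adhesion molecule, had a log2 fold change of -2.01 ± 0.45, Cybrd1, an iron-related reductase, -1.64 ± 0.38. Angptl7, a secreted protein of the angiopoietin-like family, was at 13.8 ± 8.36 and 3.46 ± 0.146 CPM.

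None of these genes passed the test over all genes. With edgeR's quasi-likelihood test, 0 of 13737 genes had an adjusted p under 0.05, and 291 had an unadjusted p under 0.05, 194 higher and 97 lower in Sfrp4-/- libraries, where 687 would be expected by chance. These counts depended on single libraries, with 1115 higher and 248 lower without wild-type replicate 1, 538 and 287 without wild-type replicate 2, 164 and 229 without Sfrp4-/- replicate 1, and 87 and 52 without Sfrp4-/- replicate 2. The lowest adjusted p was that of Sfrp4 and every other gene was at an edgeR adjusted p of 1.00. DESeq2, run without the filter on low counts (21751 genes), called 7 genes, limma-voom 0, and edgeR without that filter 20. Some of the 20 overlapped between genotypes, such as Prg2 (0 and 23.3 CPM in wild-type, 116 and 0.924 CPM in Sfrp4-/- libraries). Others were high in a single library, such as Neat1 (5.20 and 4.08 against 7.13 and 36.1 CPM). Both were named after their values were seen. Of the 7 called by DESeq2, Col10a1, Hist1h2ao and Sfrp4 were lower, and C1qc, Epx, Gm18194 and Gm42793 were higher, the names outside the fixed rule being chosen after their values were seen. Epx had 400 counts in Sfrp4-/- replicate 1 and 0 in each other library. Scaling by library totals alone moved the median log2 fold change of all genes from 0.0031 to 0.24 and the share of higher genes among those with an unadjusted p under 0.05 from 66.7% to 92.6%. All levels below are relative to the composition-corrected scale.

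**Figure D1:**
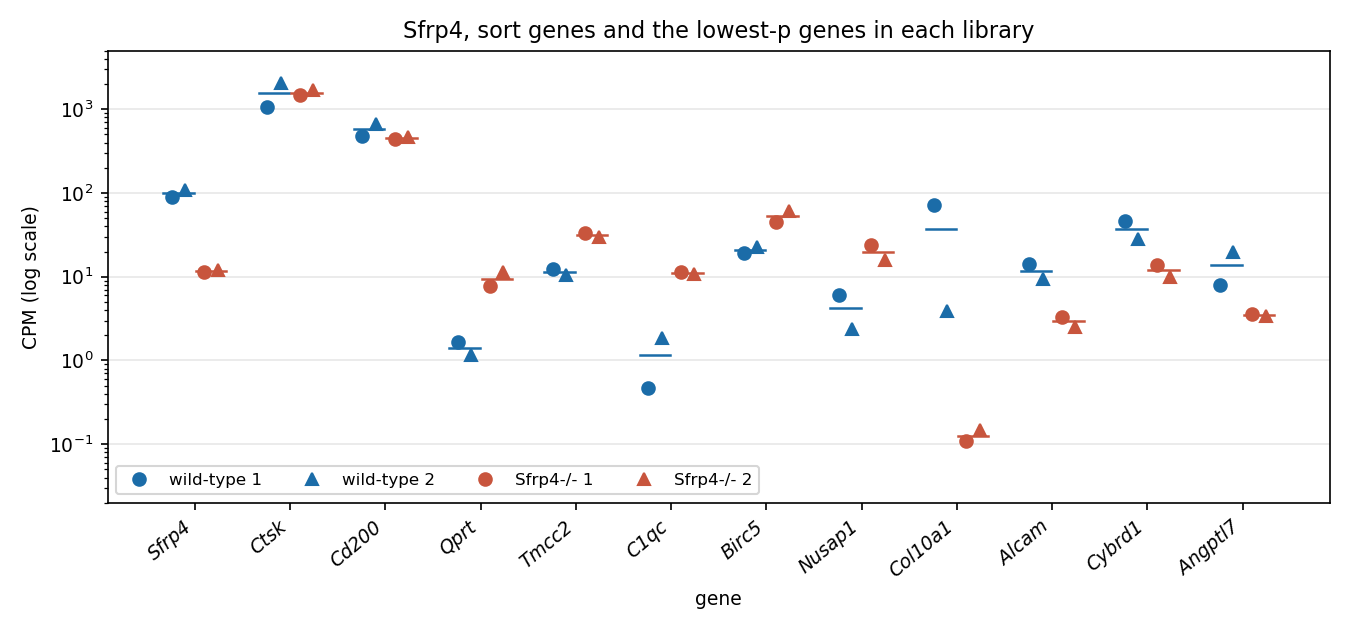
Level in CPM on a log scale of Sfrp4, 2 genes of the sort and the genes with the lowest p in each direction, in each of the 4 libraries; circles are replicate 1, triangles replicate 2, blue wild-type, red Sfrp4-/-, and short lines the mean of each genotype. Sfrp4 lies at 90.8 and 108 CPM in wild-type and at 11.4 and 12.1 CPM in Sfrp4-/- libraries, while the wild-type values of Col10a1 spread from 71.0 to 3.91 CPM.

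The list of S phase and mitosis genes was higher in the Sfrp4-/- libraries by the set test with a preset correlation, though no single member passed. It had a median log2 fold change of 0.86, or 1.82-fold, with 35 of 36 members above 0 (camera adjusted p = 6.29e-22). With the correlation between genes estimated from the libraries the call was lost (adjusted p = 0.356 with an estimated correlation). That correlation was 0.0125, near the preset 0.01, so its size alone does not account for the lost call. The estimated-correlation test also missed a simulated list of 20 genes raised 2-fold (camera adjusted p = 0.498). Calls lost with an estimated correlation, here and below, therefore cannot decide whether a list shifted. In 27 of the 36 genes both Sfrp4-/- libraries lay above both wild-type libraries, where chance gives 16.7%. That share, here and below, holds for interchangeable libraries, and these libraries also differed by replicate number. Genes of a list are not independent draws either. The count of members past the test was 0 over all genes and 0 adjusted over the list alone. Birc5, which encodes survivin, and Nusap1, a spindle protein, had the lowest p in the list. The summed level of the list was 517 and 503 CPM in wild-type and 896 and 883 CPM in Sfrp4-/- libraries.

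The erythroid list, and by a smaller median the myeloid list, were also higher by this test. All 15 measured erythroid genes were above 0, with a median of 1.19, or 2.29-fold (camera adjusted p = 4.98e-15, and adjusted p = 0.869 with an estimated correlation). The membrane genes of red cell precursors Epb42 and Rhag had log2 fold changes of 3.03 ± 0.79 and 1.79 ± 0.49 (SE, n = 2 each). In 9 of the 15 genes, and in 7 of the 23 genes of the myeloid list, both Sfrp4-/- libraries lay above both wild-type libraries (chance 16.7%). Rhag was at 4.87 and 4.78 CPM in wild-type and at 23.4 and 9.92 CPM in Sfrp4-/- libraries. The summed level of the erythroid list, carried mostly by globins, was 978 and 2407 CPM in wild-type and 2647 and 3029 CPM in Sfrp4-/- libraries. The myeloid list had a smaller median of 0.30 over 23 genes, 17 of them above 0 (camera adjusted p = 0.00186, and adjusted p = 0.869 with an estimated correlation). C1qc led it, followed by the granule gene Ltf (0.74 ± 0.36), while other members such as Mpo lay below 0. The summed level of the myeloid list was 1020 and 2024 CPM in wild-type and 1728 and 2429 CPM in Sfrp4-/- libraries. The myeloid call was lost without wild-type replicate 1 (median 0.37, camera adjusted p = 0.860). No erythroid or myeloid gene passed over all genes, and 0 passed when adjusted over the list alone. The erythroid list, like the cell cycle list, passed without any single library (medians 0.72 to 1.64 and 0.78 to 1.03).

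The matrix, cartilage, bone and secretory lists had medians below 0 and passed as lists with the preset correlation, while few of their genes separated the genotypes. The extracellular matrix list had a median of -0.44 over 38 genes, 26 of them below 0 (camera adjusted p = 1.54e-05). The chondrocyte list had a median of -0.46 over 18 genes (camera adjusted p = 0.00186) and the osteoblast list a median of -0.30 over 25 genes (camera adjusted p = 0.00252). Endoplasmic reticulum chaperone and stress genes had a median of -0.36 over 23 genes (camera adjusted p = 0.00309). All 4 calls were lost with an estimated correlation (adjusted p = 0.869 with an estimated correlation for each). Both Sfrp4-/- libraries lay below both wild-type libraries in 5 of the 38 matrix genes, 2 of the 18 cartilage genes, 4 of the 25 osteoblast genes and 5 of the 23 chaperone genes, where chance gives 16.7%. In the matrix list the collagen cross-linking enzyme Loxl2 was at 47.7 and 29.1 CPM in wild-type and 15.1 and 3.79 CPM in Sfrp4-/- libraries (log2 fold change -2.02 ± 0.64, SE), and the microfibril gene Fbn2 had -1.32 ± 0.42. Among cartilage genes Col10a1 stood lowest and was the only member of any list that passed when adjusted over the list alone (edgeR adjusted p = 0.0275), while Sox6, a chondrogenic transcription factor, lay on the other side at 1.26 ± 0.45. Of the osteoblast genes, the alkaline phosphatase gene Alpl had -0.91 ± 0.59 and the potassium channel gene Kcnk1 -0.76 ± 0.37. Xbp1, a regulator of the secretory apparatus, had -0.68 ± 0.37, and Ppp1r15a, a stress-induced phosphatase subunit, had 0.69 ± 0.28, opposite to its list. No member of these lists passed over all genes.

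These 4 calls were lost when wild-type replicate 1 or Sfrp4-/- replicate 2 was left out, which also leaves unequal replicate numbers in the genotypes. Without wild-type replicate 1 the medians were 0.045 for matrix, 0.35 for cartilage, -0.062 for osteoblast and -0.155 for chaperone genes, and without Sfrp4-/- replicate 2 they were 0.11, 0.034, -0.16 and -0.11. None of the 4 lists passed in either case, with camera adjusted p from 0.242 to 0.938. In the matrix list without wild-type replicate 1 the median and the test differed in sign, since camera gave the direction as lower. After trends with GC content, gene length and abundance were removed, the osteoblast median was 0.031, the matrix median -0.191 and the chondrocyte median -0.41. Levels also followed the replicate number within each genotype, with summed matrix genes at 17252 and 8860 CPM in wild-type replicates 1 and 2 and at 12131 and 4515 CPM in Sfrp4-/- replicates 1 and 2.

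**Figure D2:**
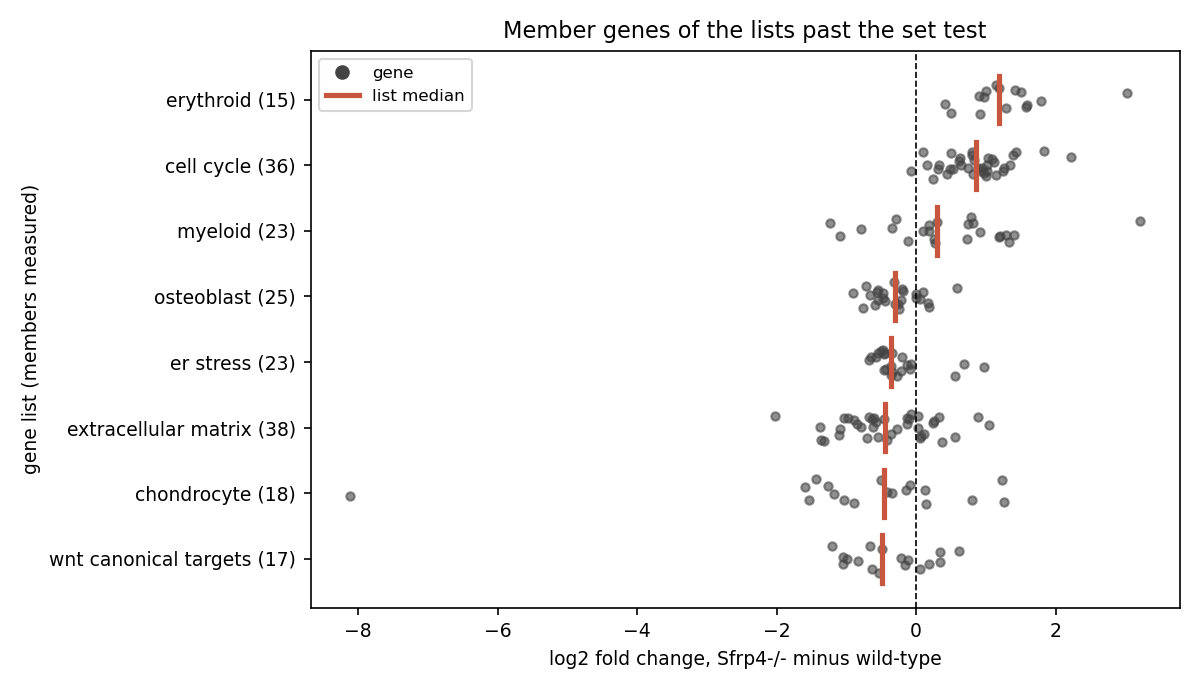
Log2 fold change (Sfrp4-/- minus wild-type) on the x axis of each measured member, as dots, of the 8 gene lists that passed camera with its preset correlation, with the list median as a red bar. Erythroid (median 1.19) and cell cycle genes (0.86) lie almost wholly above 0, while the myeloid list and the 5 lists with a median below 0 spread to both sides.

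Because Sfrp4 encodes a Wnt-binding protein, 4 lists of Wnt genes were examined. The list of canonical Wnt target genes passed with a median of -0.49 over 17 genes, 12 of them below 0 (camera adjusted p = 0.00612, and adjusted p = 0.869 with an estimated correlation). Both Sfrp4-/- libraries lay below both wild-type libraries in 4 of the 17 genes (chance 16.7%). This call too was lost without wild-type replicate 1 (median -0.064, camera adjusted p = 0.803) and without Sfrp4-/- replicate 2 (median -0.24, camera adjusted p = 0.363). Nkd2, a feedback inhibitor of the pathway, was at 40.3 ± 16.5 CPM in wild-type and 20.2 ± 0.333 CPM in Sfrp4-/- libraries (SD, n = 2 each; log2 fold change -0.99 ± 0.37, SE). The other targets named by the rule had log2 fold changes of -1.21 ± 0.60 for Apcdd1, -0.64 ± 0.33 for Bambi, -0.67 ± 0.42 for Gja1, -1.04 ± 0.70 for Nkd1 and -0.83 ± 0.62 for Notum. The 5 members above 0, named outside the fixed rule, were Znrf3 (0.62 ± 1.15), Lef1 (0.35 ± 0.56), Myc (0.34 ± 0.31), Ccnd1 (0.19 ± 0.33) and Tcf7 (0.058 ± 0.33). The targets Axin2, Lgr5, Sp5 and Rnf43 did not enter the test. Wnt antagonists other than Sfrp4, a list of secreted proteins and the membrane receptor Kremen1, did not pass as a list (median -0.27 over 10 genes, camera adjusted p = 0.0575). They passed with DESeq2 (median -0.28, camera adjusted p = 0.0378) and under other settings, and had a median of 0.0061 without wild-type replicate 1. Their named members had log2 fold changes of -0.73 ± 0.46 for Dkk3, -0.75 ± 0.55 for Sfrp1, -0.94 ± 0.70 for Frzb, -1.11 ± 0.85 for Sfrp2, -0.28 ± 0.36 for Dkk1 and -0.26 ± 0.59 for Kremen1. Ligands, R-spondins and canonical receptors did not pass either (median -0.32 over 18 genes, camera adjusted p = 0.196). Wnt4 was at 84.4 ± 46.9 and 41.2 ± 3.25 CPM (-1.04 ± 0.43), and the receptors Fzd9, Fzd5, Lrp6 and Lrp5 had -1.01 ± 0.51, -0.92 ± 0.59, -0.49 ± 0.32 and -0.72 ± 0.66, against 0.90 ± 0.66 for Rspo3. Non-canonical genes had a median of 0.10 over 28 genes (camera adjusted p = 0.464), with Wnt5b at -0.82 ± 0.43, Ryk at -0.45 ± 0.32, Nfatc3 at 0.48 ± 0.32, Dact1 at 0.63 ± 0.45, Prickle2 at 1.58 (0.488 ± 0.442 and 1.46 ± 0.761 CPM, SD) and Fzd6 at 1.73 ± 1.59. No gene of the 4 lists passed over all genes, and 0 passed when adjusted over the list alone. Notum, Dact1, Fzd5, Sfrp2 and Rspo3 share 38.1%, 34.9%, 17.8%, 16.1% and 13.1% of their exon bases with a gene on the other strand, which libraries without strand cannot separate.

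Markers of skeletal stem and progenitor cells did not shift as a list (median 0.18 over 23 genes, camera adjusted p = 0.609). Besides Angptl7, its lowest p was that of Pi16, a marker of fibroblast progenitors with 0 counts in both wild-type libraries and 36 counts in the Sfrp4-/- libraries, at least 9.87-fold higher against a floor of 3 counts over the group. With Pi16 at that bound the median of the list stayed at 0.18. Tendon and fibrous layer genes had a median of -0.32 (camera adjusted p = 0.0715), with Dcn, a proteoglycan of collagen fibrils, at 11197 ± 2016 and 6848 ± 1935 CPM (SD, n = 2 each; log2 fold change -0.71 ± 0.42) and Cilp at -2.55 ± 1.55. Adipocyte genes had a median of 0.069 (camera adjusted p = 0.464), with Lpl at 0.62 ± 0.31 and Adipoq at 2.58 ± 1.67. Matrix proteases and their inhibitors had a median of -0.095 (camera adjusted p = 0.0752), with Mmp23 at -0.83 ± 0.39 and Ctsl, which shares 26.8% of its exon bases with other genes, at -0.70 ± 0.40. Over left-out libraries the median ranged from -1.16 to 0.12 for tendon genes and from -0.65 to 0.038 for protease genes. Both of these lists passed with DESeq2 and with the replicate block. None of the stem, tendon, adipocyte and protease lists had a member past the test over all genes or when adjusted over the list alone.

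Other signalling and stress lists did not pass in the main test. Immediate early genes passed with DESeq2, with the replicate block and with at least 5 CPM in 2 libraries. BMP and TGF-beta genes passed without a filter on low counts. BMP and TGF-beta genes had a median of -0.18 (camera adjusted p = 0.145), with Ltbp2 at -1.94 ± 0.77 and Inhbb at -1.55 ± 0.67 (log2 fold change ± SE, here and in the rest of the paragraph). Notch genes had a median of -0.25 (camera adjusted p = 0.590), with Heyl at -0.49 ± 0.37 and Jag1 at -1.19 ± 1.13. Hedgehog genes had a median of -0.24 but a mean of 0.16, and camera gave their direction as higher (adjusted p = 0.898), with Gli3 at 1.28 ± 0.62 and Hhip at 1.25 ± 1.38. Genes induced by p53 had a median of -0.18 (camera adjusted p = 0.504), with Btg2 at 0.69 ± 0.32 and Pmaip1 at 0.57 ± 0.42. Immediate early genes, which respond to tissue dissociation, had a median of 0.30 (camera adjusted p = 0.222), with Fos at 1.06 ± 0.36 and Junb at 0.78 ± 0.31. Chemokine and cytokine genes had a median of 0.15 (camera adjusted p = 0.473), with Vcam1 at 0.83 ± 0.35 and Il1b at 1.36 ± 0.58. Interferon-stimulated genes had a median of -0.25 (camera adjusted p = 0.473), with Rsad2 at 1.03 ± 0.39 and Usp18 at -1.12 ± 0.49. Glycolytic and hypoxia genes had a median of -0.034 but a mean of 0.13, with a direction of higher in camera (adjusted p = 0.898). Among them Ankrd37 was at 0.450 ± 0.307 and 5.54 ± 1.64 CPM (3.62 ± 0.78), with 26.4% of its exon bases shared with other genes, and Adm had -0.61 ± 0.38. In these lists 0 genes passed over all genes and 0 when adjusted over the list alone.

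Markers of other cell types that a sort can carry over were also counted. Lymphoid and antigen presentation genes had a median of 0.31 (camera adjusted p = 0.145), with Cd79a at 0.77 ± 0.31 and Igkc at 0.92 ± 0.49 (log2 fold change ± SE, as in what follows). Endothelial genes had a median of -0.97 (camera adjusted p = 0.609), with Emcn at -2.47 ± 1.89 and Plvap at -0.87 ± 0.70. Their sum was 65.7 CPM in wild-type replicate 1 against 8.05, 23.9 and 14.6 CPM in the other libraries. In wild-type replicate 2, 7 of the 10 genes had 0 counts, so that the direction of the list depends on which wild-type library is kept. Mural cell genes had a median of -0.33 (camera adjusted p = 0.232), with Kcnj8 at -1.82 ± 1.00 and Myl9 at 0.70 ± 0.41. Skeletal muscle genes had a median of 0.67 and a sum between 3.93 and 11.6 CPM (camera adjusted p = 0.145). Tnni2 had 4 counts in the wild-type and 35 in the Sfrp4-/- libraries, a ratio of 7.20 with a 95% counting interval of 2.57 to 27.9, and Mylpf had 1.15 ± 0.76. Schwann and neural genes had a median of -0.14, a mean of 0.22 and a camera direction of lower (adjusted p = 0.993), with S100b at 1.70 ± 0.76 and Tubb3 at -0.68 ± 0.35. Osteoclast genes other than Ctsk had a median of 0.15 (camera adjusted p = 0.609), with Sh3pxd2a at -0.36 ± 0.31 and Tnfrsf11a at 0.45 ± 0.42. Their sum was 3170 and 3630 CPM in wild-type and 4087 and 3770 CPM in Sfrp4-/- libraries, far above the endothelial and muscle sums. Whether osteoclasts passed the sort was not tested. Keratinocyte genes had a median of 0.31 over 3 genes (camera adjusted p = 0.628), with Perp at 1.02 ± 0.79 and Lor at -0.43 ± 0.48. Among sex-linked genes (median -0.094, camera adjusted p = 0.628), Kdm5d had -0.30 ± 0.51 and Ddx3y -0.16 ± 0.30. Ddx3y was at 27.9 to 36.6 CPM in all 4 libraries, and Xist had 0, 0, 0 and 3 counts. No gene in these lists passed over all genes, and 0 passed when adjusted over the list alone.

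Mitochondrially encoded genes, read as a sign of cell and RNA quality, differed with the replicate number. Genes of the mitochondrial chromosome took 0.715% and 1.74% of the counts in wild-type replicates 1 and 2 and 0.835% and 2.10% in Sfrp4-/- replicates 1 and 2. Between genotypes the mitochondrially encoded list had a median of 0.078 over 10 genes (camera adjusted p = 0.609), with mt-Nd6 at 0.40 ± 0.35 and mt-Co2 at 0.74 ± 0.67 (SE). Levels within the list were uneven, with mt-Co2 between 5.27 and 23.1 CPM and mt-Co1, named after its values were seen, between 1862 and 4100 CPM. The reason was not tested, so the mt-Co2 value is uncertain. Nuclear genes of the respiratory chain had a median of 0.23 over 36 genes (camera adjusted p = 0.145) and passed with DESeq2 (median 0.22, camera adjusted p = 0.0162) and among genes of at least 5 CPM in 2 libraries (median 0.26, camera adjusted p = 0.0248), with Uqcrb at 0.78 ± 0.52 and Atp5g1 at 0.55 ± 0.43. The direction of both lists depended on the library left out. Without Sfrp4-/- replicate 2 the medians were -0.53 and -0.24 (camera adjusted p = 0.00496 and 0.0215), without wild-type replicate 2 they were 0.74 and 0.80 (camera adjusted p = 0.00331 and 4.22e-06), and without Sfrp4-/- replicate 1 they were 0.55 and 0.61 (camera adjusted p = 2.55e-04 and 4.07e-09). In both lists 0 genes passed over all genes and 0 when adjusted over the list alone.

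**Figure D3:**
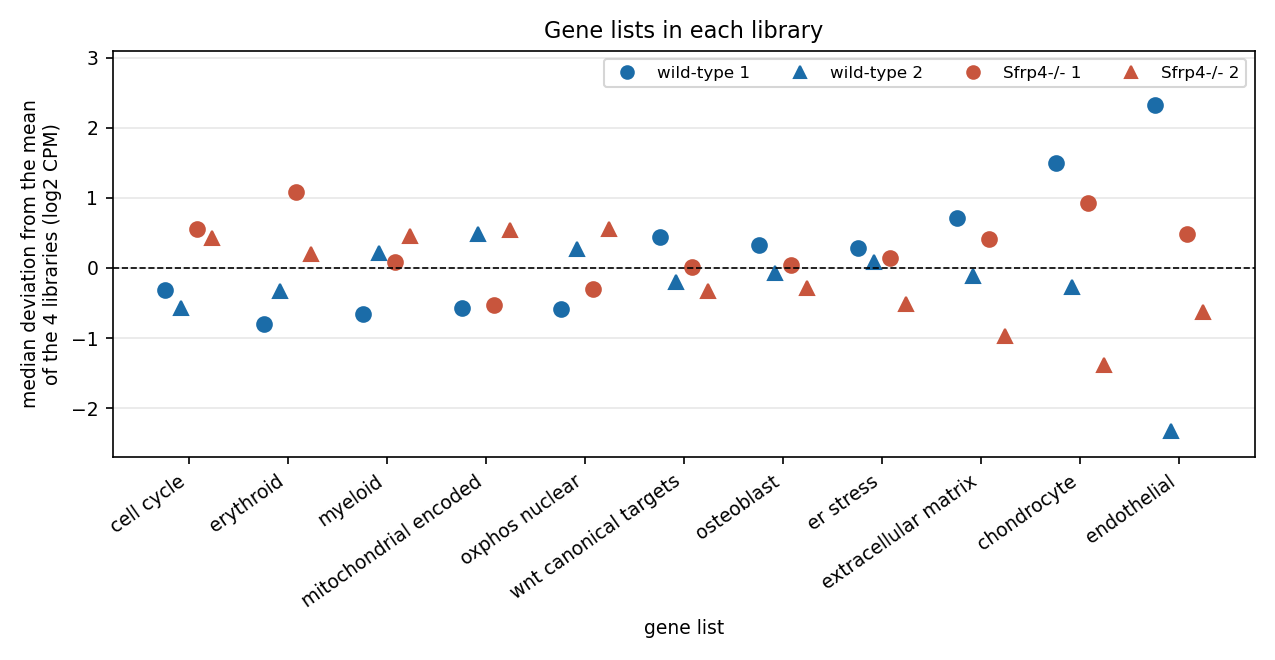
Median deviation of each gene list in each library from the mean of the 4 libraries, in log2 CPM on the y axis; circles are replicate 1, triangles replicate 2, blue wild-type, red Sfrp4-/-. In the cell cycle list both Sfrp4-/- libraries (0.55 and 0.43) lie above both wild-type libraries (-0.32 and -0.57), whereas mitochondrially encoded genes separate by replicate number, at -0.57 and -0.53 in the replicates 1 and 0.48 and 0.55 in the replicates 2.

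The most similar libraries were the replicates 1 of both genotypes. Pearson correlations of log2(CPM + 1) across the tested genes were 0.945 between the wild-type libraries and 0.964 between the Sfrp4-/- libraries. Between genotypes they were 0.974 for the replicates 1, 0.963 for the replicates 2, and 0.947 and 0.956 for the other pairs. The mean within genotypes minus the mean between genotypes was -0.0055, a difference in which the pairs between genotypes include those of the same number and the pairs within genotypes do not. Among pairs of different numbers, those within (0.945 and 0.964) and between genotypes (0.947 and 0.956) overlapped. These correlations are across genes, which are not independent replicates.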

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

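Set tests with an estimated correlation and a block, and gene families, were chosen after seeing the data; the other alternatives were planned. The count of 0 changed genes became 20 (15 higher, 5 lower) without a filter on low counts, 7 (4 higher, 3 lower) with DESeq2 and 1 (1 lower, Sfrp4) with the replicate block, and it ranged from 0 to 2 over the left-out libraries, all lower. It stayed 0 under the other settings, at an adjusted p under 0.10 and against 1.5-fold. The gene calls of DESeq2 were also made without the filter (21751 genes against 13737), so they differ from the main test in filter and method together. Of 8 lists past the threshold, there were 15 with DESeq2, 13 with the replicate block, and 0 with an estimated correlation, with fry, and with the replicate block and an estimated correlation together. Leaving out a library gave 3 to 18 lists: 3 without wild-type replicate 1 (2 of the 8 shared), 6 without Sfrp4-/- replicate 2 (3 shared), 18 without wild-type replicate 2 and 16 without Sfrp4-/- replicate 1 (8 shared each). The cause was not tested. The log2 fold change of Sfrp4 passed at -3.08 without a filter, -3.09 with DESeq2 and -3.07 with the replicate block (adjusted p = 0.0218), and its adjusted p ranged from 2.58e-12 to 0.997 over its alternatives. The numbers are shared by 2 pairs of libraries and the labels do not say that they mark a batch; the correlation of same-numbered deviations was 0.256, and with the block 401 genes were higher and 463 lower at an unadjusted p under 0.05. Reversed single genes were Eng (0.11 with library totals, 0.66 with limma-voom, 0.45 with the replicate block), Kremen1 (0.0013 with limma-voom), Emcn (0.32 with limma-voom) and Ddx3y (0.067 with library totals). Over left-out libraries the sign turned for Ctsk (-0.38 to 0.58), Ptprc (-0.076 to 0.47), Eng (-1.05 to 2.19), Frzb (-1.99 to 0.19), Sfrp2 (-2.19 to 0.32), Dkk1 (-0.60 to 0.050), Kremen1 (-0.89 to 0.86), Hhip (-1.87 to 3.85), Emcn (-3.47 to 5.85), Plvap (-1.60 to 0.68), Tnfrsf11a (-0.10 to 0.86), mt-Co2 (-0.45 to 1.49), Uqcrb (-0.12 to 1.33), Atp5g1 (-0.0094 to 0.96) and Ddx3y (-0.34 to 0.049), none of which passed the main test. With an estimated correlation the test alone differs, so the medians of the 8 lists stayed at 0.86 for cell cycle, 1.19 for erythroid, 0.30 for myeloid, -0.44 for extracellular matrix, -0.46 for chondrocyte, -0.30 for osteoblast, -0.36 for chaperone and -0.49 for canonical Wnt target genes, without a call. Lists that passed only under an alternative were, with DESeq2, Wnt antagonists (-0.28), Wnt ligands and receptors (-0.29), tendon (-0.51), matrix proteases (-0.10), immediate early (0.29), endothelial (-0.99) and nuclear respiratory chain genes (0.22). With the replicate block all 8 lists kept their call (camera adjusted p = 2.81e-14 for extracellular matrix, 2.15e-12 for chondrocyte, 7.08e-07 for osteoblast and 1.02e-05 for chaperone genes), and the added lists were Wnt antagonists (-0.32), tendon (-0.39), matrix proteases (-0.14), immediate early (0.30) and nuclear respiratory chain genes (0.23). With at least 5 CPM in 2 libraries they were Wnt ligands and receptors (-0.30), matrix proteases (-0.33), immediate early (0.39) and nuclear respiratory chain genes (0.26). Wnt antagonists passed with library totals (-0.043), without a filter (-0.27) and with limma-voom (-0.35), tendon genes with library totals (-0.12) and without a filter (-0.50), and BMP and TGF-beta genes without a filter (-0.090). Over left-out libraries the medians of lists whose call changed ranged from -2.07 to 0.35 for chondrocyte, -1.34 to 0.11 for extracellular matrix, -0.53 to -0.062 for osteoblast, -0.73 to -0.11 for chaperone, -0.65 to -0.064 for canonical Wnt target and 0.24 to 1.04 for myeloid genes. Among lists without a call in the main test they ranged from -0.78 to 0.0061 for Wnt antagonists, -0.83 to 0.34 for Wnt ligands and receptors, -1.16 to 0.12 for tendon, -0.65 to 0.038 for matrix proteases, -0.40 to 0.10 for BMP and TGF-beta, 0.015 to 0.36 for immediate early, -0.67 to 0.20 for interferon, 0.029 to 0.69 for lymphoid, -1.97 to 5.97 for endothelial, -0.75 to 0.14 for mural, -0.043 to 1.70 for muscle, -0.53 to 0.74 for mitochondrially encoded and -0.24 to 0.80 for nuclear respiratory chain genes. The highest values of the endothelial list and of Emcn, without wild-type replicate 1, are set against 0 counts in the remaining wild-type library for Emcn and 7 of the 10 genes and are no measure of size. Of 1258 alternatives for the 92 named genes, 1220 kept direction and side of the threshold, 15 newly passed and 23 reversed. Of 112 for the 8 passing lists, 93 kept both, 16 lost the call, 8 of them with an estimated correlation, and 3 reversed, and with fry, not in these counts, all 8 lost the call; of 360 for the 26 others, 316 kept their side, 41 newly passed and 3 turned and passed. Within-genotype similarity stayed below that between genotypes under all 4 alternatives (-0.0073 to -0.0027). Depth limits genes such as Pi16 and Tnni2, with 36 and 39 counts over the 4 libraries.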

Other observations

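The families, the split of the libraries by number, the single genes named here, the marker-list tests of leukocytes and erythroid cells, the test without wild-type replicate 1 and the chromosome 13 test, with their criteria, were chosen after the values were seen; the GC, length and abundance tests were not. Split by replicate number, the libraries gave 2135 genes at an unadjusted p under 0.05, against 291 for genotype and 139 for the crossed split (0 at an adjusted p under 0.05 with edgeR in each), which points to a structure of the samples other than genotype. In the replicates 2, nuclear respiratory chain genes (median 0.86, camera adjusted p = 1.17e-19) and mitochondrially encoded genes (median 1.06, camera adjusted p = 2.78e-15) were higher, while extracellular matrix genes (median -1.08, camera adjusted p = 2.4e-15), chondrocyte genes (median -1.87, camera adjusted p = 1.26e-11) and endothelial genes (median -2.85, camera adjusted p = 1.93e-05) were lower. Of the 8 lists that passed for genotype, 6 also passed in this split: besides matrix and chondrocyte genes, these were osteoblast (median -0.48, camera adjusted p = 6.56e-04), canonical Wnt target (median -0.48, camera adjusted p = 0.00397), chaperone (median -0.39, camera adjusted p = 0.0106) and, higher in the replicates 2, myeloid genes (median 0.28, camera adjusted p = 0.00926). The cell cycle list (median -0.12, camera adjusted p = 0.390) and the erythroid list (median -0.67, camera adjusted p = 0.698) did not pass in it.

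Ribosomal protein genes had a median log2 fold change of 0.29 between genotypes over 81 genes, 68 above 0 (camera adjusted p = 0.0140 over 15 families, and adjusted p = 0.810 with an estimated correlation). Their median was above 0 under each scaling but was -0.15 without wild-type replicate 1 and -0.33 without Sfrp4-/- replicate 2. Eosinophil granule genes differed between libraries of a genotype: Prg2 had 0 and 400 counts in wild-type and 2140 and 19 in Sfrp4-/- libraries, and Epx had 400 counts in Sfrp4-/- replicate 1 alone. The nuclear RNAs Malat1 and Neat1 were at 447 and 36.1 CPM in Sfrp4-/- replicate 2, against at most 104 and 7.13 CPM in the other libraries.

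The cell cycle list was higher in both Sfrp4-/- libraries (median 0.86). After trends with GC content, gene length and abundance were removed, its median was 0.948, above all 10000 random lists matched on abundance, which argues against such trends as the whole cause. Erythroid precursors, which divide rapidly, are a candidate source despite the Ter119 gate: the erythroid list, 0 of whose 15 genes are in another list, had a median of 1.19, at least that of the cell cycle list. That comparison does not show that such cells supply enough cell cycle transcripts. In wild-type replicates 1 and 2 the summed erythroid level was 978 and 2407 CPM, while that of cell cycle genes was 517 and 503 CPM. In Sfrp4-/- replicates 1 and 2 the sums were 2647 and 3029 CPM against 896 and 883 CPM. The erythroid sums are carried mostly by globins. By median deviation from the mean of the libraries (log2 CPM), erythroid genes were at 1.08 and 0.20 in Sfrp4-/- replicates 1 and 2, and cell cycle genes at 0.55 and 0.43. In wild-type replicates 1 and 2 they were at -0.81 and -0.33 against -0.32 and -0.57. The lists thus did not move by like amounts within a genotype. The most abundant erythroid genes were Hba-a1, at 229 and 602 CPM in wild-type and 695 and 936 CPM in Sfrp4-/- libraries, and Hbb-bs, whose genotypes overlapped, at 392 and 1321 against 1018 and 1414 CPM. Leukocytes, which the CD45 gate should remove, cannot be told apart from no contribution, since the myeloid and lymphoid genes had a median of 0.303 with a median absolute deviation of 0.589 and Ngp was at 155 and 425 against 491 and 609 CPM; greater proliferation of the Sfrp4-/- periosteal cells remains open, untested.

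The extracellular matrix list was lower in Sfrp4-/- libraries (median -0.44). With the trends removed its median was -0.191, below the central 95% of matched random lists (-0.05 to 0.20). The osteoblast median moved from -0.30 to 0.031, inside its random range, and the chondrocyte median from -0.46 to -0.41, below all 10000 of its own. The random lists held genes matched on abundance alone, while the estimated correlation was 0.655 in the matrix list and 0.584 in the chondrocyte list. Medians of correlated genes vary more, so these ranges cannot decide whether the trends account for the whole shift. The trends were fitted over all genes, list members included, so removing them can also remove a real change in abundant genes. Whether they cause any part of these shifts therefore cannot be told. Without wild-type replicate 1 the matrix median was 0.0447 (camera adjusted p = 0.803), and without Sfrp4-/- replicate 2 it was 0.11 (camera adjusted p = 0.539). A high matrix content of wild-type replicate 1 alone cannot be told apart from the structure by replicate number, since either left-out library leaves an unequal mix of numbers; among libraries of the same number the summed matrix genes were lower in Sfrp4-/- both times, at 17252 against 12131 and 8860 against 4515 CPM. A genotype effect remains open.

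Genes with a low p lay near Sfrp4 on chromosome 13. Within 10 Mb of it 8.43% of genes (7 of 83, Sfrp4 left out) had an unadjusted p under 0.05, against 2.07% of the other 13653 (Fisher's exact test, one-sided, p = 0.00184); 53 of 12731 windows centred on genes of other chromosomes had as high a share. Sequence of another strain kept around the targeted allele is a candidate explanation: Gpr137b (chromosome 13, 13357620 to 13394014) was at 38.8 and 53.5 CPM in wild-type and 101 and 129 CPM in Sfrp4-/- libraries, while its near-copy Gpr137b-ps was at 34.1 and 31.7 against 2.11 and 20.5 CPM, and Hist1h2ao was at 5.33 and 8.69 against 0.864 and 0.486 CPM. It cannot be told apart from a change in histone genes, which make up 16 of the 83 genes: without them the share was 5.97% (4 of 67, Fisher's exact test, one-sided, p = 0.0516). Histone genes did not shift as a family (median 0.39 over 21 genes, 12 above 0, camera adjusted p = 0.332). Of the 3 histone genes near Sfrp4 with a low p, Hist1h2ao was lower while Hist1h4i and Hist1h1d were higher. Neighbouring genes are not independent, and the strains were not given in the sources used here.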
